A study of Mus musculus with 9 samples.

How the data were processed

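Total RNA was measured on 9 single-channel Affymetrix Mouse Gene 1.0 ST arrays, which carry probes along whole transcripts. Per the labels, the RNA came from small-intestinal intraepithelial lymphocytes of NOD-SCID mice aged 8 to 10 weeks, taken as CD3- CD45+ cells and sorted to a purity over 98%. RNA was isolated with the RNeasy Plus Micro kit, amplified with the NuGEN Ovation Pico WTA V2 kit and labelled with the Affymetrix WT Terminal Labeling kit. The labels name 3 populations, Ly49E+CD8aa+, Ly49E+CD8aa- and Ly49E-CD8aa+, with 3 arrays each numbered as biological replicates. The number of mice behind an array is not given in the sources used here.

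The deposited values were log2 expression values from RMA, per the submitters' processing notes, with 1 value per transcript cluster (a row of the table) and array. The log2 scale was read from the values themselves, which ran from 1.84 to 13.8 with none negative. The RMA version, the genome build and the annotation used by the authors are not given in the sources used here, nor is any centring after RMA. The array medians were 5.81, 5.78 and 5.77 in Ly49E+CD8aa+, 5.76, 5.76 and 5.81 in Ly49E+CD8aa-, and 5.82, 5.82 and 5.78 in Ly49E-CD8aa+. No calls of detection were used here, so a low value does not show that a transcript was missing. The number of arrays limits the precision, and the median standard error (SE) of a log2 difference between populations was 0.0976.

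Of 35556 rows, 23410 were listed in the platform annotation, 21789 of them with 1 gene symbol and 1621 with several, and 12146 were not listed. Of the rows with 1 symbol, 21698 were matched to a current gene record by identifier. Rows with 1 symbol were tested without a filter on dim rows. In the 999 genes with more than 1 such row, the row with the highest mean over the arrays stood for the gene, which left 19938 genes. No positions are given, since no build was named. Members of families of near-identical sequence, such as the Klra, granzyme and H2 genes, were taken as open to cross-hybridisation. 1 of the fixed genes was not analysed here.

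Each pair of populations was compared with limma 3.58.1 in R 4.3.3. A linear model with a mean for each population was fitted to all 9 arrays, with empirical Bayes moderation of the variances (prior degrees of freedom 3.08, residual degrees of freedom 6) and no block. Tests were 2-sided, and a gene was called higher or lower when its Benjamini-Hochberg adjusted p over the 19938 genes was under 0.05, with no minimum difference. The moderated F test over the 3 populations used the same threshold. Differences are log2 values of the first-named population minus the second, with the SE from the model, and levels are means with the standard deviation (SD) over 3 arrays.

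The lists were fixed before the data were examined, as were the comparisons, the rule for named genes and all alternatives but 1. The 29 lists covered sort markers, Ly49 (Klra) receptors, NK cell receptors and adaptors, conventional NK cell genes, ILC1 and tissue residency genes, ILC2 genes, ILC3 genes, T lineage genes, transcription factors of NK cells and innate lymphoid cells (ILCs), granzymes and cytotoxic effectors, cytokines and chemokines, their receptors, and intraepithelial adhesion and retention genes. They also covered MHC class II presentation, markers of enterocytes, secretory epithelium, macrophages and monocytes, dendritic cells, B and plasma cells, mast cells, granulocytes, erythroid cells, and stroma and endothelium, and genes of proliferation, the immediate early and stress response, the interferon response, oxidative phosphorylation, glycolysis and apoptosis. Each list with at least 4 measured members was tested with camera of limma, with a preset correlation of 0.01 between genes and adjustment over the 29 lists. The test was repeated with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance.

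For each comparison the named genes were the sort markers and a few fixed factors and receptors whatever their test, the 8 called genes with the largest difference each way whose arrays did not overlap, and up to 4 called members of each list with the largest difference. Predicted genes and antigen receptor segments were left out of the 8. Genes named outside this rule are said to be chosen after their values were seen. Genes called in a pair of comparisons were counted and set beside the number that independent lists would share and beside 100 simulations without differences, which give few calls and so do not measure what shared arrays add to real differences. The position of Ly49E+CD8aa+ between the other populations was the median over genes called between those populations, with 0 at the level of Ly49E-CD8aa+ and 1 at that of Ly49E+CD8aa-.

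The alternatives were the 6 arrays of a comparison alone, filters at the 25th percentile and at the median of row means, quantile normalization again, centring on array medians, an intensity trend with robust variance, array weights, the mean of a gene's rows, every row of the table, the replicate number as a block, a minimum log2 difference of 1, and leaving out each array. A fit without the arrays of estimated weight under 0.7 was added after seeing the data. The test was also tested on simulated data with 200 shifted genes and a list of 25 further genes shifted by 0.5. Of the 200 genes, those shifted by 0.5, 1 and 2 log2 units were recovered in 49.2%, 88.1% and 97.4% of cases (32, 52 and 74 genes) in Ly49E+CD8aa+ against Ly49E-CD8aa+. With 10 genes of the list and 13 false calls, a share over 0.05, this made 181 calls. The data gave 26 calls in this comparison, and with fewer true differences the adjusted threshold is stricter. The simulated shares may therefore overstate what was recovered in the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.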

Results

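Innate intraepithelial lymphocytes of the mouse small intestine were divided by Ly49E and CD8aa, and the transcriptomes of 3 sorted populations were measured on 3 arrays each. Ly49E is a receptor of the Ly49 family, known from NK cells and encoded by Klra5. CD8aa is the homodimer of the CD8 alpha chain, encoded by Cd8a and carried by many intraepithelial lymphocytes. NOD-SCID mice lack mature T and B cells. Pearson correlations between arrays, taken across rows that are not independent replicates, were 0.9907 to 0.9937 between Ly49E+CD8aa+ and Ly49E-CD8aa+ and 0.9849 to 0.9875 between Ly49E+CD8aa- and Ly49E-CD8aa+. Over the 3 populations, 405 of 19938 genes differed by the F test, and 248 without Ly49E+CD8aa- replicate 3.

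The transcripts of the sort markers followed the labels in part. Klra5, open to cross-hybridisation, was at 11.40 ± 0.103 in Ly49E+CD8aa+ and 11.43 ± 0.0654 in Ly49E+CD8aa-, and at 6.59 ± 0.982 in Ly49E-CD8aa+ (log2, SD, n = 3), where the arrays read 6.99, 5.48 and 7.31. Cd8a was at 12.55 ± 0.0668 and 12.58 ± 0.0669 in the CD8aa+ populations and at 11.42 ± 0.143 in Ly49E+CD8aa-. Cd8b1, which encodes the CD8 beta chain, went the other way, with 8.34 ± 0.216 in Ly49E+CD8aa- and 5.28 ± 0.0271 and 5.30 ± 0.132 in Ly49E+CD8aa+ and Ly49E-CD8aa+. Cd3e, which encodes a chain of the CD3 complex, was at 11.75 ± 0.0374, 11.67 ± 0.0884 and 10.70 ± 0.467 in Ly49E+CD8aa+, Ly49E-CD8aa+ and Ly49E+CD8aa-. Ptprc, which encodes CD45, was at 11.83 ± 0.089, 11.82 ± 0.0136 and 11.85 ± 0.043 in Ly49E+CD8aa+, Ly49E+CD8aa- and Ly49E-CD8aa+ and did not pass in any comparison. The list of 5 sort markers was not called by camera (adjusted p = 0.19, 0.722 and 0.352 for the Ly49E comparison, the CD8aa comparison and the comparison of the populations with a single marker).

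**Figure D1:**
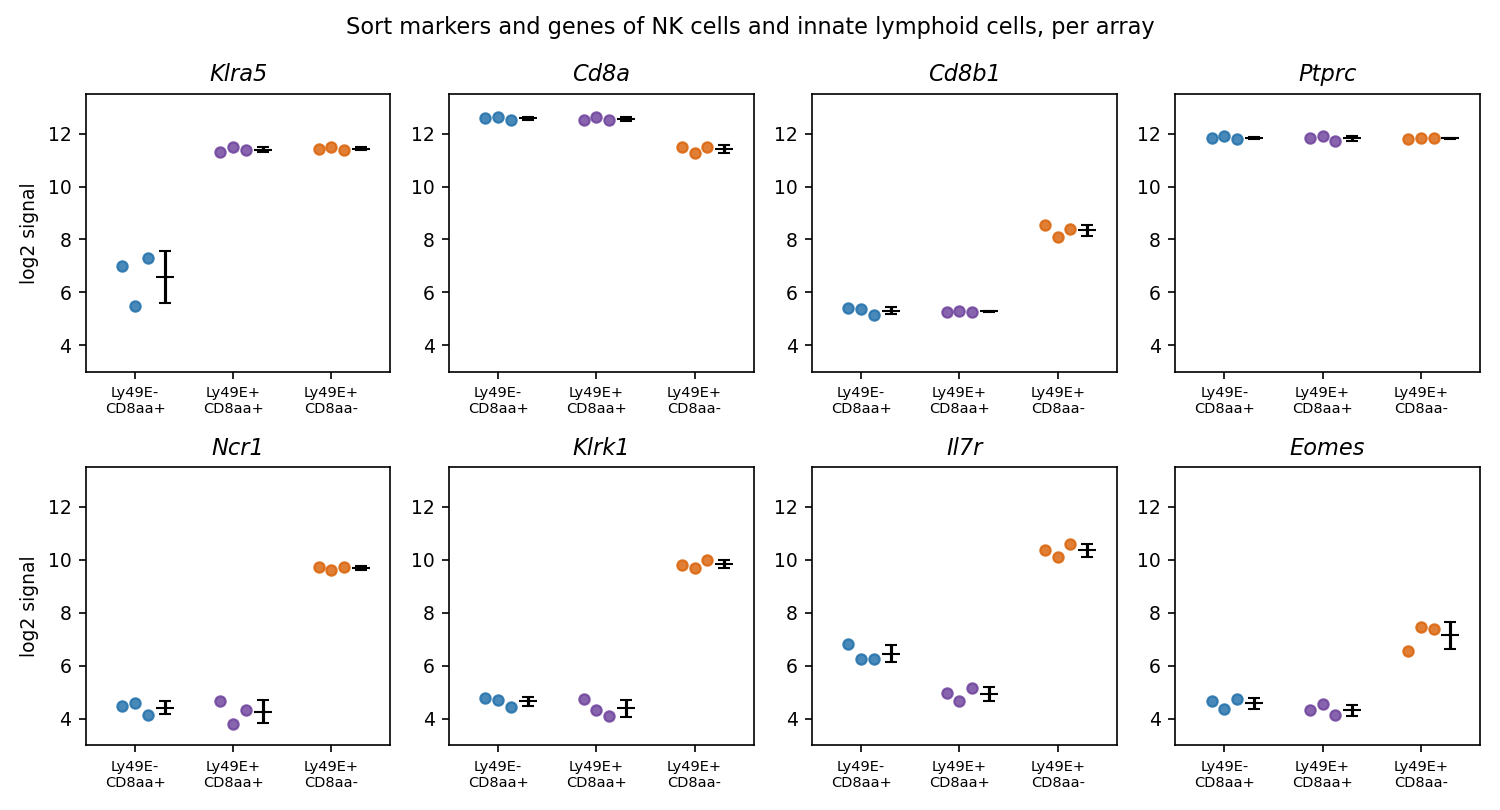
Log2 signal (y axis) of selected genes on each array of the 3 populations (x axis), with dots for arrays and bars for the mean and SD of 3 arrays. Ncr1 averaged 9.69 in Ly49E+CD8aa- and 4.26 and 4.40 in the CD8aa+ populations, while Klra5 averaged 6.59 in Ly49E-CD8aa+ and 11.40 and 11.43 in the Ly49E+ populations.

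Among CD8aa+ cells, those with and without Ly49E differed in few genes, apart from Ly49E itself. Klra5 was higher in Ly49E+CD8aa+ than in Ly49E-CD8aa+ by 4.80 (SE 0.383, adjusted p = 0.0029, n = 3 per population), a 27.9-fold difference. Klrb1b, an NK receptor of the Nkrp1 family, was higher by 1.01 (SE 0.125), Adh1, an alcohol dehydrogenase, by 0.83 (SE 0.0924), and Cd226, an activating receptor that binds nectin-like ligands, by 0.80 (SE 0.0971). On the lower side, Siglech, a lectin of plasmacytoid dendritic cells, had a log2 difference of -1.98 (SE 0.131, adjusted p = 0.00099), Cd180, a Toll-like receptor homologue, of -2.21 (SE 0.135, adjusted p = 0.000952), and Cybb, the NADPH oxidase subunit of phagocytes, of -2.48 (SE 0.207, adjusted p = 0.0029).

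In all, 4 genes were higher and 22 lower in Ly49E+CD8aa+ than in Ly49E-CD8aa+. Further lower genes were Rnase6 (-2.56), Lgals1, which encodes galectin 1 (-2.09), Ifitm3, an interferon-induced membrane protein (-1.92), Pld4 (-1.91), the lectin Cd209d (-1.87), Il7r, the IL-7 receptor alpha chain (-1.52), Klra17 (-1.51), Ly6d (-1.28) and Blnk, a B cell adaptor (-0.74), with SEs from 0.0834 to 0.352 and adjusted p from 0.0029 to 0.0438. Klra17 is open to cross-hybridisation. With the replicate number as a block, 17 genes passed in this comparison in place of 26, and Cd226, Pld4 and Ifitm3 did not (limma adjusted p = 0.0785, 0.0904 and 0.121). The values for Cd8a (-0.03), Tbx21 (-0.12), Gata3 (-0.04), Eomes (-0.26), Ncr1 (-0.15) and Klrb1c (0.10) did not pass.

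Dendritic cell markers were lower in Ly49E+CD8aa+ than in Ly49E-CD8aa+ as a group, with a median of -0.40 (camera adjusted p = 6.13e-19). Of 17 measured members, 2 were lower over all genes, Siglech and Ly6d, and 11 were lower adjusted over the list alone. This was the 1 call of this comparison that held with an estimated correlation (adjusted p = 0.0141). The MHC class II list, partly open to cross-hybridisation, was lower with a median of -0.24 (adjusted p = 3.31e-10, and adjusted p = 0.195 with an estimated correlation), with 0 of 14 members past the threshold over all genes and 6 lower adjusted over the list alone. NK cell receptors and adaptors were higher with a median of 0.08 (adjusted p = 0.00912, and adjusted p = 0.605 with an estimated correlation). Of their 30 members, Klrb1b and Cd226 were higher over all genes and 5 were higher and 1 lower adjusted over the list alone. The call was lost without Ly49E+CD8aa+ replicate 3 (adjusted p = 0.0589) and without Ly49E-CD8aa+ replicate 1 (adjusted p = 0.491), and without the latter array 5 lists in place of 3 were called in this comparison.

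By limma, 834 of 19938 genes had an unadjusted p under 0.05 in this comparison, less than the share of 0.05 that chance alone would give. In 1247 (6.25%, against 10% by chance) the arrays did not overlap. The count of 22 lower genes became 4, 4 and 6 without Ly49E+CD8aa+ replicates 1, 2 and 3, 5, 4 and 8 without Ly49E+CD8aa- replicates 1, 2 and 3, and 8, 28 and 8 without Ly49E-CD8aa+ replicates 1, 2 and 3, and the 4 higher genes became 1, 1, 1, 1, 2, 2, 1, 4 and 2 in the same order. With the 6 arrays of this comparison alone limma called 0 genes, with 695 at an unadjusted p under 0.05, also below the share that chance would give. Of the 16 named calls, 0 passed in all of the up to 19 alternatives run per gene, the block and the minimum difference not counted. Those of Siglech, Cd180 and Cybb were lost in the fit of the 6 arrays and in no other, those of Klra5 and Ly6d in 2, and those of Klrb1b, Cd226, Il7r, Lgals1 and Ifitm3 in 11, 11, 11, 12 and 13 of the 19.

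**Figure D2:**
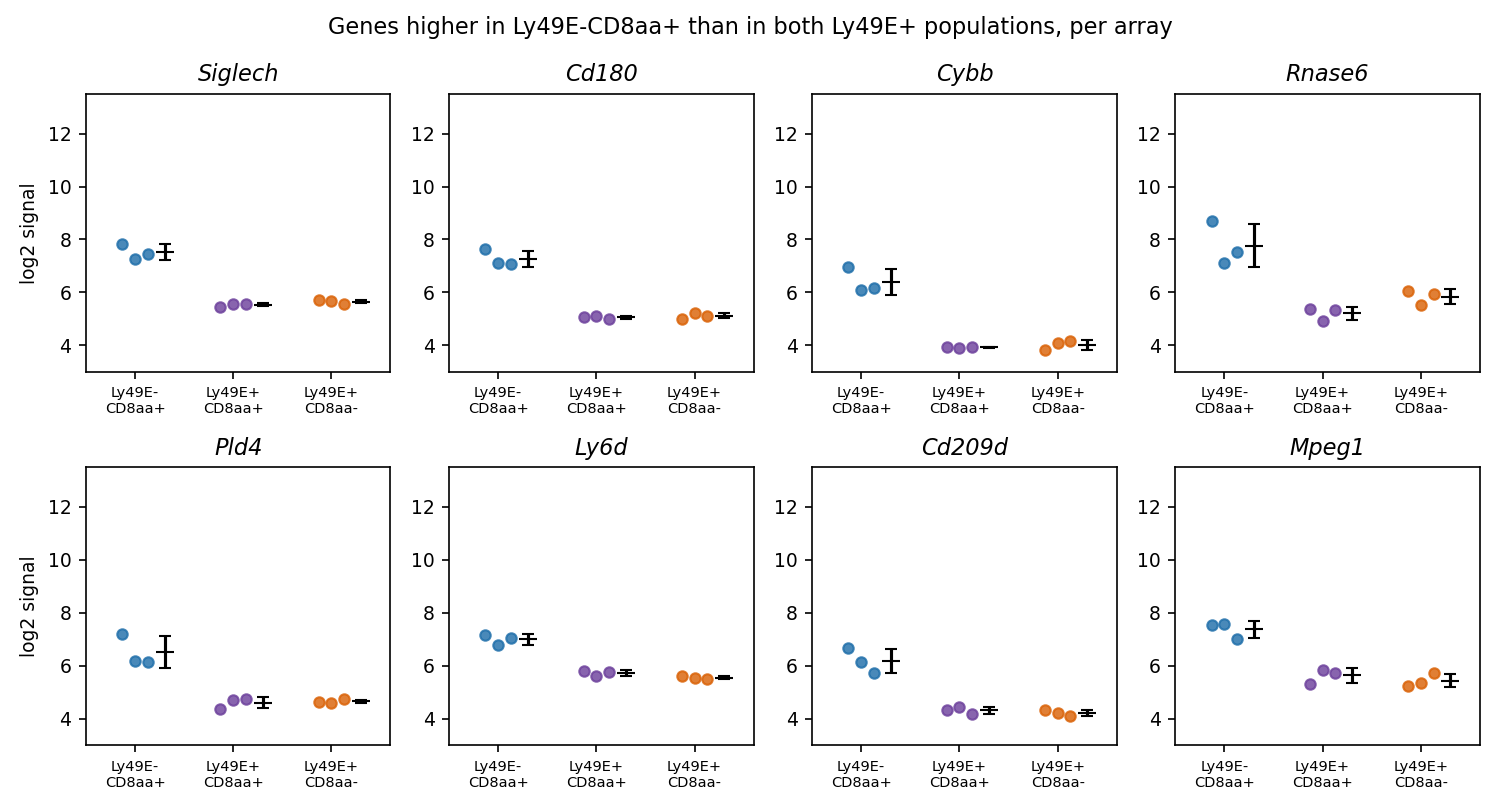
Log2 signal (y axis) on each array of the 3 populations (x axis) for 8 genes higher in Ly49E-CD8aa+ than in both Ly49E+ populations, with dots for arrays and bars for the mean and SD of 3 arrays. Siglech averaged 7.51 in Ly49E-CD8aa+, 5.54 in Ly49E+CD8aa+ and 5.65 in Ly49E+CD8aa-.

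Among Ly49E+ cells, CD8aa separated populations with very different receptors. Ly49E+CD8aa+ cells had lower levels of the activating NK receptors Klrk1 (NKG2D; log2 difference -5.46, SE 0.163, adjusted p = 3.94e-07) and Ncr1 (NKp46; -5.44, SE 0.202, adjusted p = 1.02e-06) than Ly49E+CD8aa- cells (n = 3 per population). The IL-7 receptor gene Il7r (-5.44, SE 0.192), the IL-18 receptor gene Il18r1 (-5.13, SE 0.129) and Klrc1, which encodes NKG2A (-5.05, SE 0.168), were lower too. Genes higher in Ly49E+CD8aa+ differed less. They included Adh1 (2.05, SE 0.0924, adjusted p = 3.82e-06), the glutathione peroxidase family gene Gpx8 (1.44, SE 0.128), Rnf180 (1.44, SE 0.143), the phosphatase gene Ptpn5 (1.26, SE 0.0882) and Cd8a (1.13, SE 0.0841, adjusted p = 0.000113).

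Of 19938 genes, 95 were higher and 244 lower in Ly49E+CD8aa+, 16 and 142 of them by a log2 difference of at least 1. NK cell receptors and adaptors were lower as a group, with 15 of 30 members lower over all genes and 17 lower and 1 higher adjusted over the list alone (adjusted p = 4.67e-23). Klre1 (-4.01) was among them. Of 5 measured Ly49 receptors (of 21 in the fixed list), open to cross-hybridisation, Klra8 (-1.66) and Klra6 (-0.71) were lower over all genes and 4 were lower adjusted over the list alone (adjusted p = 2.59e-07). Klra8 and Klra6 lay at low levels, 3.89 and 4.14 in Ly49E+CD8aa+ and 5.55 and 4.85 in Ly49E+CD8aa-. The 25th percentiles of the arrays ran from 4.40 to 4.47. Cytokine and chemokine receptors were lower, 11 of 29 over all genes against 2 higher, and 13 lower and 2 higher adjusted over the list alone (adjusted p = 1.67e-13). Il2ra, the IL-2 receptor alpha chain, had a difference of -3.41 and Il23r of -3.72.

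ILC3 genes were lower, 6 of 19 over all genes and 14 adjusted over the list alone (adjusted p = 6.36e-21), among them Ffar2, a receptor for short-chain fatty acids (-2.47), Rora (-2.11) and the lymphotoxin beta gene Ltb (-1.87). Transcription factors were lower, with 5 lower and 1 higher of 32 over all genes and 11 lower and 1 higher adjusted over the list alone (adjusted p = 4e-09). Eomes, a T-box factor of NK cells, had a difference of -2.83, Maf of -0.75 and Gata3 of -0.51 (adjusted p = 0.0366), while Tbx21, at -0.32, did not pass (adjusted p = 0.0871), nor did Klrb1c at -0.34. Cytokines and chemokines were called lower (adjusted p = 0.00104), with 4 of 25 lower over all genes and 7 lower and 1 higher adjusted over the list alone, although the median was 0.03. The 4 were Csf2 (-3.75), Tnf (-3.25), Ltb and Tnfsf14 (-1.51). The immediate early and stress list moved with Tnf and Csf2, with 6 of 27 members lower over all genes and 14 adjusted over the list alone (adjusted p = 1.81e-13). Nr4a1 (-2.29), Gadd45b (-1.59), Fosb (-1.45) and Nfkbia (-1.24) were its named members. These 7 lists held with an estimated correlation, with adjusted p from 0.00663 to 0.0351.

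The other 9 calls did not hold with an estimated correlation. ILC1 and tissue residency genes were lower in 6 and higher in 2 of 24 members over all genes and in 9 and 6 adjusted over the list alone (adjusted p = 0.000101, and adjusted p = 0.0555 with an estimated correlation). The membrane proteins Tmem176b (-4.44) and Tmem176a (-4.23) were among them. T lineage genes were lower in 4 and higher in 2 of 23 over all genes and in 7 and 4 adjusted over the list alone (adjusted p = 0.00731, and adjusted p = 0.139 with an estimated correlation). Thy1 (-3.95), Cd2 (-2.58) and Cd28 (-2.54) fell, while Themis (1.28) and Cd3e (1.05) were higher. Conventional NK cell genes were lower in 3 and higher in 2 of 18 over all genes and in 6 and 3 adjusted over the list alone (adjusted p = 0.0168, and adjusted p = 0.142 with an estimated correlation), with Lgals1 at -3.80, Klrg1 at -1.09 and the perforin gene Prf1 at 0.58. Granzymes and cytotoxic effectors, open to cross-hybridisation, were higher with 1 of 23 higher over all genes, Prf1, and 2 adjusted over the list alone (adjusted p = 0.0464, and adjusted p = 0.184 with an estimated correlation). This call was lost without Ly49E+CD8aa+ replicates 2 and 3 (adjusted p = 0.0623 and 0.11), Ly49E+CD8aa- replicates 1 and 3 (0.122 and 0.0861) and Ly49E-CD8aa+ replicates 2 and 3 (0.0545 and 0.0618). ILC2 genes (adjusted p = 0.0512) and adhesion and retention genes (adjusted p = 0.0831) did not pass.

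MHC class II genes and dendritic cell markers were lower in Ly49E+CD8aa+ as well. The class II list had 1 of 14 members lower over all genes and 3 adjusted over the list alone (adjusted p = 0.000573, and adjusted p = 0.179 with an estimated correlation). The dendritic cell list had 2 of 17 lower over all genes and 3 adjusted over the list alone (adjusted p = 0.0168, and adjusted p = 0.179 with an estimated correlation). Its lower members were H2-Aa (-1.08), a class II chain open to cross-hybridisation, and Irf4 (-0.69), a transcription factor of many lymphocytes. Proliferation genes were lower by a median of -0.105, with 0 of 24 past the threshold over all genes or adjusted over the list alone (adjusted p = 0.00104, and adjusted p = 0.179 with an estimated correlation). Interferon-stimulated genes were lower by a median of -0.13, with 0 of 23 over all genes and 2 adjusted over the list alone (adjusted p = 0.000138, and adjusted p = 0.11 with an estimated correlation). Glycolysis genes were lower by a median of -0.163, with 0 of 16 over all genes and 2 adjusted over the list alone (adjusted p = 0.00079, and adjusted p = 0.175 with an estimated correlation).

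Further named genes of this comparison were the costimulatory receptor gene Icos (-3.86), Pram1 (-4.28), the integrin gene Itgal (-2.80), the chemokine receptor genes Ccr2 (-2.17) and Ccr9 (-1.59), Crtam (-1.52), Cd226 (-1.04) and Kit (-1.17) on the lower side. Cela1 (1.38), Pdzk1 (1.30), Islr (1.16), Alas2, an enzyme of haem synthesis (0.58), and the type 2 cytokine gene Il13 (0.58) were higher. By limma, 1880 genes had an unadjusted p under 0.05, and the arrays did not overlap in 2579 (12.9%, against 10% by chance). The count of 95 higher genes became 55, 58 and 55 without Ly49E+CD8aa+ replicates 2 and 3 and Ly49E+CD8aa- replicate 3. Of the 54 named calls, 42 passed in all alternatives run per gene, the block and the minimum difference not counted, and those lost in 1 or more included Themis, Islr, Cd3e, Prf1, Alas2, Gata3, Irf4, H2-Aa, Klrg1, Fosb, Cela1 and Pdzk1.

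The populations with a single marker differed in 429 genes. Ly49E+CD8aa- cells were higher than Ly49E-CD8aa+ cells in Ncr1 (5.29, SE 0.202, adjusted p = 1.42e-06), Klrk1 (5.20, SE 0.163), Il18r1 (5.12, SE 0.129), Klrc1 (5.08, SE 0.168), Klra5 (4.84, SE 0.383) and Klrb1b (4.59, SE 0.125), with n = 3 per population. They were lower in Cybb (-2.39, SE 0.207, adjusted p = 0.000282), Cd180 (-2.16, SE 0.135), Cd209d (-1.97, SE 0.197), Mpeg1, a perforin-like protein of phagocytes (-1.95, SE 0.197), Siglech (-1.87, SE 0.131) and Cd8a (-1.16, SE 0.0841). In all, 269 genes were higher and 160 lower, 154 and 35 of them by at least 1 log2 unit.

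NK cell receptors and adaptors were higher in Ly49E+CD8aa-, 16 of 30 over all genes and 19 higher and 4 lower adjusted over the list alone (adjusted p = 1.68e-23). The Ly49 receptors Klra8 (1.65), Klra3 (1.61) and Klra6 (1.19) were higher and Klra17 (-0.93) lower, 3 and 1 of 5 over all genes and also adjusted over the list alone (adjusted p = 0.000385), all open to cross-hybridisation. In Ly49E-CD8aa+, Klra8, Klra3 and Klra6 read 3.90, 3.77 and 3.66, below the 25th percentiles of the arrays (4.40 to 4.47). ILC3 genes were higher in 6 of 19 over all genes and 14 adjusted over the list alone (adjusted p = 4.07e-19), with Il23r at 3.96, Ffar2 at 2.71, Rora at 2.13 and Ltb at 2.08. Cytokine and chemokine receptors were higher in 10 and lower in 1 of 29 over all genes and in 12 and 4 adjusted over the list alone (adjusted p = 4.72e-10), with Il7r at 3.92 and Il2ra at 3.50. Transcription factors were higher in 5 and lower in 1 of 32 over all genes and in 13 and 3 adjusted over the list alone (adjusted p = 3.66e-07), with Eomes at 2.57, Maf at 0.99 and Lef1 at 0.66. Gata3 was at 0.47 (adjusted p = 0.0456), while Tbx21 (0.20) and Klrb1c (0.44) did not pass.

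Cytokines and chemokines were higher in 5 of 25 over all genes and in 8, with 1 lower, adjusted over the list alone (adjusted p = 8.35e-05), with Csf2 at 3.44, Tnf at 3.12 and Tnfsf14 at 1.35. Immediate early and stress genes were higher beside them, 6 of 27 over all genes and 13 adjusted over the list alone (adjusted p = 4.45e-16), with Nr4a1 at 2.08, Gadd45b at 1.88, Nfkbia at 1.12 and Dusp1 at 0.82. These 2 lists and the 5 of NK receptors, Ly49 receptors, ILC3 genes, cytokine receptors and transcription factors held with an estimated correlation, with adjusted p from 0.00955 to 0.0334.

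Of the calls that did not, ILC1 and tissue residency genes were higher in 6 and lower in 2 of 24 over all genes and in 9 and 7 adjusted over the list alone (adjusted p = 6.77e-05, and adjusted p = 0.0505 with an estimated correlation), with Tmem176b at 4.53 and Tmem176a at 4.26. T lineage genes were higher in 6 and lower in 1 of 23 over all genes and in 8 and 3 adjusted over the list alone (adjusted p = 0.000962, and adjusted p = 0.0674 with an estimated correlation), with Thy1 at 3.89, Cd2 at 2.41, Cd28 at 2.36 and Cd3e at -0.98. ILC2 genes were called higher although their median was -0.00647, with 4 higher and 1 lower of 16 over all genes and adjusted over the list alone (adjusted p = 0.00434, and adjusted p = 0.0674 with an estimated correlation). Icos (3.86), Klrg1 (1.36) and Rora were higher and Il13 (-0.56) lower. Adhesion and retention genes were higher in 6 and lower in 2 of 19 over all genes and in 6 and 6 adjusted over the list alone (adjusted p = 0.0306, and adjusted p = 0.0956 with an estimated correlation), with Itgal at 2.48, Ccr9 at 2.00, Cd226 at 1.84 and Crtam at 1.77. That call was lost without Ly49E+CD8aa- replicate 2 (adjusted p = 0.0711) and Ly49E-CD8aa+ replicate 1 (adjusted p = 0.0898). Granzymes and cytotoxic effectors were lower, with Prf1 (-0.76) the 1 of 23 past the threshold over all genes and adjusted over the list alone (adjusted p = 0.0307, and adjusted p = 0.182 with an estimated correlation), a call lost without Ly49E+CD8aa- replicates 1 and 3 (adjusted p = 0.0877 and 0.0717) and Ly49E-CD8aa+ replicates 2 and 3 (0.218 and 0.109).

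Dendritic cell markers were lower in Ly49E+CD8aa- than in Ly49E-CD8aa+, 4 of 17 over all genes against 1 higher, and 8 lower and 2 higher adjusted over the list alone (adjusted p = 6.77e-05, and adjusted p = 0.062 with an estimated correlation). Siglech, Ly6d (-1.45) and Cd209a (-1.10) were lower, and Batf3, a factor that lymphocytes express too, was higher (0.83). B and plasma cell markers were lower by a median of -0.153, with Blnk (-0.60) the 1 of 13 past the threshold over all genes and 2 adjusted over the list alone (adjusted p = 0.0184, and adjusted p = 0.229 with an estimated correlation), and the call was lost without Ly49E+CD8aa- replicate 2 (adjusted p = 0.076). Interferon-stimulated genes were higher by a median of 0.21, with 0 of 23 over all genes and 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.00133, and adjusted p = 0.136 with an estimated correlation). Glycolysis genes were higher by a median of 0.211, with 0 of 16 past the threshold over all genes or adjusted over the list alone (adjusted p = 0.00134, and adjusted p = 0.18 with an estimated correlation).

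Pram1 (4.53), Lgals1 (1.71), Kit (1.29) and Ccr2 (1.02) were higher in Ly49E+CD8aa- as well, and Rnase6 (-1.93), Pld4 (-1.86), Alox5ap, of leukotriene synthesis (-1.77), Alas2 (-0.49) and the survival gene Bcl2 (-0.34) were lower. By limma, 2081 genes had an unadjusted p under 0.05, and the arrays did not overlap in 2539 (12.7%, against 10% by chance). The count of 160 lower genes became 94 and 82 without Ly49E+CD8aa- replicates 1 and 3 and 105 and 102 without Ly49E-CD8aa+ replicates 2 and 3. Of the 61 named calls, 47 passed in all alternatives run per gene, the block and the minimum difference not counted, and those lost in 1 or more included Batf3, Gata3, Bcl2, Alas2, Cd3e, Dusp1, Lef1, Rnase6, Klra17, Ccr2, Lgals1, Nfkbia, Il13 and Alox5ap.

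Besides the sort markers, 9 lists were not called in any of the 3 comparisons. Enterocyte markers had an adjusted p of 0.0876 in the Ly49E comparison, 0.722 in the CD8aa comparison and 0.289 between the populations with a single marker. In the same order the adjusted p was 0.254, 0.569 and 0.694 for secretory epithelium, 0.33, 0.795 and 0.814 for macrophages and monocytes, 0.473, 0.795 and 0.368 for mast cells, and 0.7, 0.927 and 0.731 for granulocytes. It was 0.794, 0.927 and 0.648 for erythroid markers, 0.848, 0.227 and 0.254 for stroma and endothelium, 0.254, 0.883 and 0.182 for oxidative phosphorylation, and 0.856, 0.927 and 0.902 for apoptosis.

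**Figure D3:**
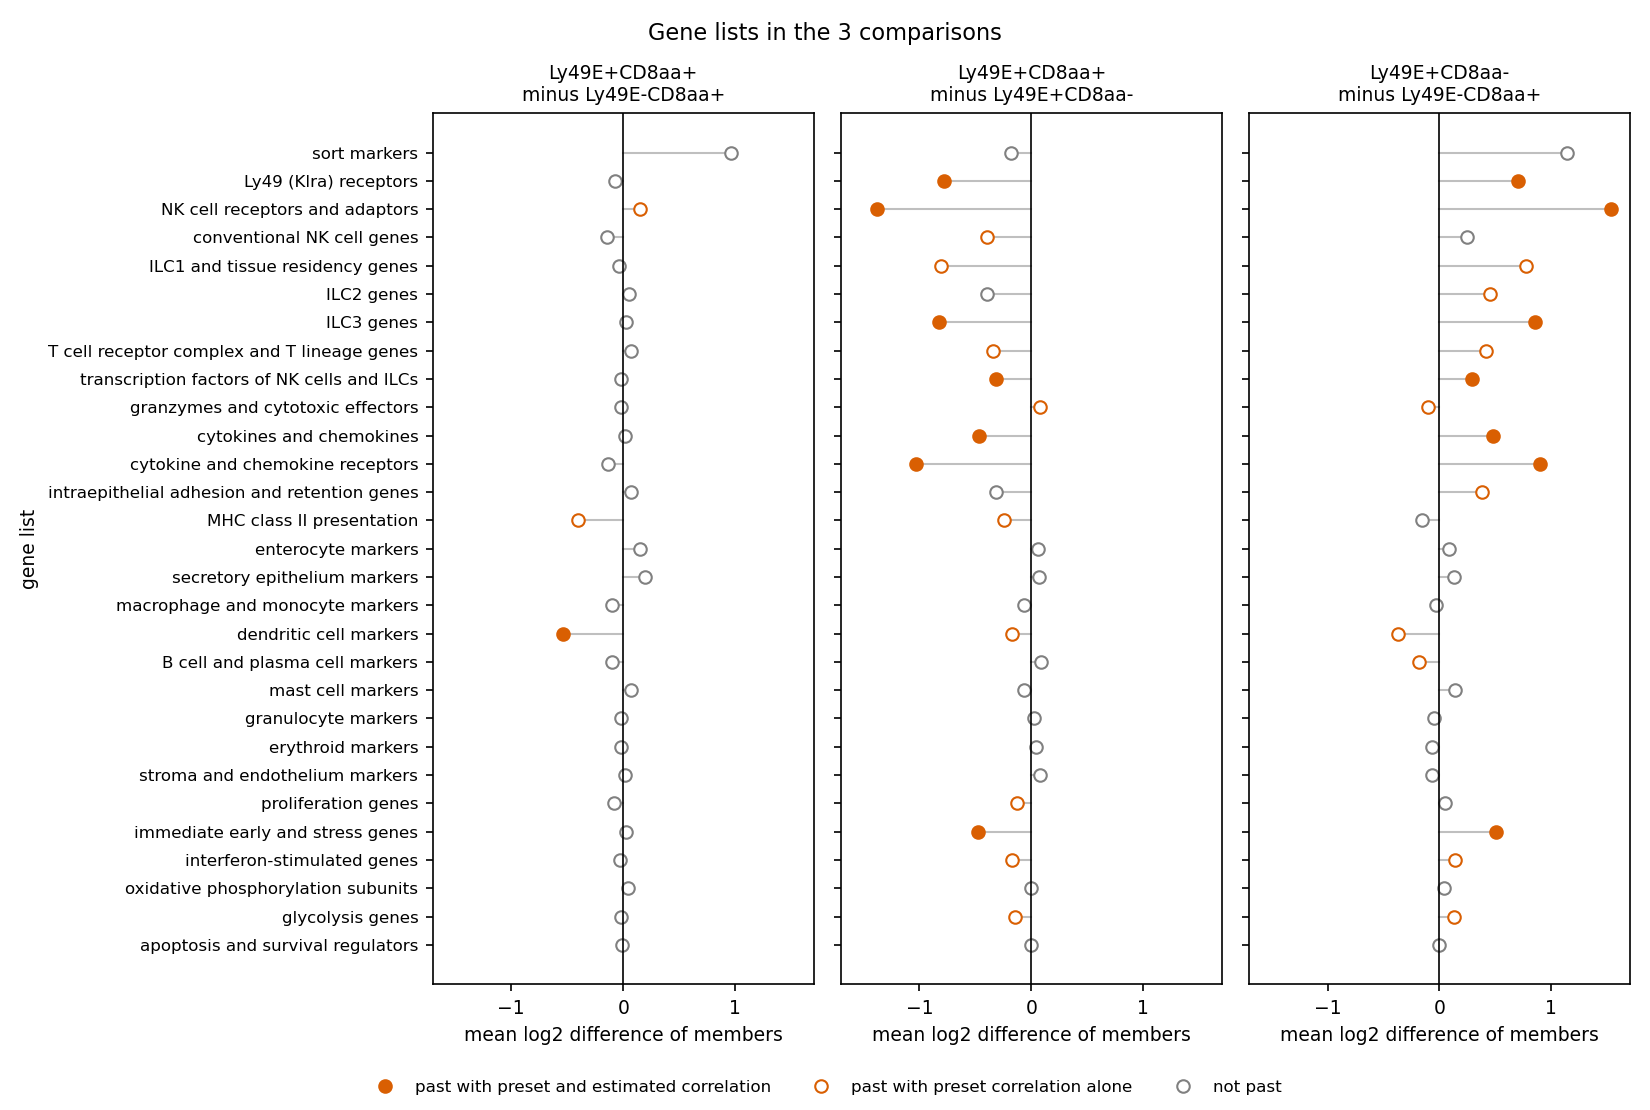
Mean log2 difference of the members (x axis) of each of the 29 lists (y axis) in the 3 comparisons, with filled symbols for lists called with both correlations, open orange symbols for those called with the preset correlation alone and grey symbols for the rest. The NK cell receptors averaged 0.147, -1.38 and 1.53 in the Ly49E comparison, the CD8aa comparison and between the populations with a single marker.

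Genes shared between comparisons set Ly49E+CD8aa- apart. Both CD8aa+ populations were lower than Ly49E+CD8aa- in 215 genes, among them Ncr1, Klrk1 and Il18r1, and higher in 72, among them Cd8a, Adh1 and Rnf180. Both Ly49E+ populations were higher than Ly49E-CD8aa+ in 3 genes, Klra5, Klrb1b and Cd226, and lower in 17, among them Siglech, Cd180, Cybb, Cd209d, Mpeg1 and Ly6d. Ly49E+CD8aa+ was higher than both other populations in Adh1 alone and lower in 4 genes, Ctsh, Ifitm3, Il7r and Lgals1, of which Ctsh was chosen after its values were seen. Independent lists would share 3.29, 0.762, 0.054, 0.177, 0.0191 and 0.269 genes in the order given, and 100 simulations without differences, which gave at most 2 calls over the 3 comparisons together, shared 0 in each case. With so few calls there is almost nothing to share, and this 0 does not measure what the shared arrays add. Part of the excess may come from the shared arrays, which cannot be divided between comparisons with 3 per population. Without replicates 1, 2 and 3 of Ly49E+CD8aa+, of Ly49E+CD8aa- and of Ly49E-CD8aa+ in turn, the 72 genes became 46, 38, 42, 44, 48, 33, 47, 47 and 41, and the 17 genes became 4, 4, 5, 4, 4, 7, 7, 21 and 8. In the same order the 3 genes became 1, 1, 1, 1, 1, 1, 1, 3 and 2, the 4 genes became 0, 0, 1, 0, 0, 0, 1, 5 and 0, and Adh1 passed in both comparisons without Ly49E+CD8aa- replicates 2 and 3 and Ly49E-CD8aa+ replicate 2.

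Over the 429 genes that differed between Ly49E+CD8aa- and Ly49E-CD8aa+, Ly49E+CD8aa+ lay at a median position of 0.106 ± 0.0311 (SD, n = 3) on the way from Ly49E-CD8aa+ at 0 to Ly49E+CD8aa- at 1. The 3 arrays gave 0.138, 0.0764 and 0.103, and the median was 0.0695 without Ly49E+CD8aa+ replicate 1 and 0.0479 over the genes that differed by at least 1 log2 unit. The genes were chosen with the same arrays that set 0 and 1, which can by itself move the position above 0. The SD covers the Ly49E+CD8aa+ arrays alone and not the error of the levels at 0 and 1. In 372 of the genes (86.7%) Ly49E+CD8aa+ was nearer Ly49E-CD8aa+, and in 57 nearer Ly49E+CD8aa-, with Klra5, Siglech, Cd180 and Cybb among the 57.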

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

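Rows outside the gene comparisons were put to the same test, since they hold signal that the comparisons leave out. Among the 1621 rows with several gene symbols, 3 passed the threshold in Ly49E+CD8aa+ against Ly49E-CD8aa+, 10 in Ly49E+CD8aa+ against Ly49E+CD8aa- and 11 in Ly49E+CD8aa- against Ly49E-CD8aa+. Among the 12146 rows without an annotated gene, 8, 32 and 49 passed in the same order. No explanation was tested for these rows.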

How the results depend on the processing

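The fit without the arrays of estimated weight under 0.7, Ly49E+CD8aa+ replicate 1 (0.659) and Ly49E-CD8aa+ replicate 1 (0.508), was chosen after seeing the data. The array number limits the precision, and signal over background could not be judged without calls of detection. Comparisons are Ly49E+CD8aa+ against Ly49E-CD8aa+ (Ly49E), Ly49E+CD8aa+ against Ly49E+CD8aa- (CD8aa) and Ly49E+CD8aa- against Ly49E-CD8aa+ (single marker). No called gene or list changed direction in any alternative. Of the 131 calls of named genes, 3 were lost with array weights, 3 with centring, 2 with quantile normalization again, 1 with an intensity trend, 28 over every row, 35 with the 6 arrays alone, 29 without the arrays of low weight, 202 of 1179 with 1 array left out, and 0 with the mean of rows. The filters at the 25th percentile and at the median of row means left 127 and 109 of these calls to test, with 0 lost. Of 35 list calls, 20 were lost with an estimated correlation, 8 with fry, 1 with quantile normalization again, 4 without the arrays of low weight and 15 of 315 with 1 array left out. Above the median of row means 3 were lost of the 32 that could be tested. Unless a cause is given, the cause was not tested.

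With an estimated correlation the called lists numbered 1, 7 and 7. Over every row of the table, which counts rows in place of genes and adds 1621 rows with several symbols and 12146 not listed, the Ly49E comparison had 10 higher and 10 lower, the CD8aa comparison 59 higher and the single-marker comparison 99 lower. Above the median of row means, with fewer genes tested, the Ly49E comparison had 12 lower, and 6 genes were lower in both Ly49E+ populations. A log2 minimum of 1 removes genes by construction. It left 2 higher in the Ly49E comparison, 16 higher and 142 lower in the CD8aa comparison, and 154 higher and 35 lower in the single-marker comparison. It also left 11 genes lower in both Ly49E+ populations, 10 higher and 132 lower in both CD8aa+ populations, 0 highest in Ly49E+CD8aa+, and a position of 0.0479. With the 6 arrays alone, and so fewer samples, limma called 0 higher and 0 lower in the Ly49E comparison (292 and 403 at an unadjusted p under 0.05, together below the share of 0.05 that chance would give), 62 higher in the CD8aa comparison and 78 lower in the single-marker comparison.

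With the replicate number as a block, the Ly49E comparison had 3 higher and 14 lower genes and 5 lists, and 11 genes were lower in both Ly49E+ populations. Of the 26, 339 and 429 calls of the comparisons, 15, 309 and 360 were also among the 17, 374 and 417 under the block. Of the 131 calls of named genes 8 did not pass under the block. They were Cd226, Pld4 and Ifitm3 in the Ly49E comparison (adjusted p = 0.0785, 0.0904 and 0.121), and Batf3, Lef1, Gata3, Bcl2 and Alas2 in the single-marker comparison (0.066, 0.051, 0.0575, 0.0831 and 0.0668). Of 35 list calls 1 did not pass under the block, granzymes and cytotoxic effectors in the CD8aa comparison (adjusted p = 0.0694). Correlations of deviations from the population means between arrays of the same number ran from -0.0627 to 0.222, with 4 of 9 over 0.1. Between arrays of other numbers they ran from -0.169 to 0.103. The pairs of replicate 1 gave 0.172, 0.222 and 0.127, and the 1 other pair over 0.1, of replicate 3, gave 0.123. The main fit, without a block, ignores what arrays of a number may share.

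Without the 2 arrays of low weight, with fewer samples, 244 genes passed the F test. In the Ly49E comparison 0 were higher and 4 lower, in the CD8aa comparison 48 were higher and in the single-marker comparison 92 lower. In the Ly49E comparison 417 were higher and 562 lower at an unadjusted p under 0.05 by limma, together just below the share of 0.05 that chance would give. Then 0 genes were higher and 4 lower in both Ly49E+ populations, 28 higher in both CD8aa+ populations, and 0 highest and 0 lowest in Ly49E+CD8aa+.

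Leaving out each array in turn gave 1 to 4 higher and 4 to 28 lower genes in the Ly49E comparison, 55 to 87 and 184 to 234 in the CD8aa comparison, and 186 to 250 and 82 to 130 in the single-marker comparison. The F test gave 248 to 332, and the called lists numbered 2 to 5, 15 to 17 and 14 to 17. Genes higher in both Ly49E+ populations numbered 1 to 3 and lower ones 4 to 21, those higher in both CD8aa+ populations 33 to 48 and lower ones 163 to 185, and those highest and lowest in Ly49E+CD8aa+ 0 to 1 and 0 to 5. The position ran from 0.0695 to 0.141.

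A sign changed in 13 cases, all in values that passed in no fit. In the Ly49E comparison, with 1 array left out, Cd8b1 ran from -0.0988 to 0.0243, Gata3 from -0.133 to 0.0230, Ncr1 from -0.344 to 0.0876 and Ptprc from -0.0673 to 0.0217, and without the arrays of low weight Cd8b1 was at 0.0333. In the CD8aa comparison Klra5 ran from -0.0902 to 0.0107, at 0.0107 without the arrays of low weight, and Ptprc from -0.0374 to 0.0516.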

Other observations

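Apart from the 4 counts over other splits of the arrays, the tests in this part were chosen only after the result was seen, as were the genes named in the next 3 paragraphs.

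Ly49E+CD8aa- cells were higher than both CD8aa+ populations in further genes outside the rule for named genes. Ms4a4b, a membrane protein of T and NK cells, was at 8.53 ± 0.116 (SD, n = 3) against 4.59 ± 0.311 in Ly49E+CD8aa+ and 4.59 ± 0.116 in Ly49E-CD8aa+, a log2 difference of 3.94 (SE 0.145, limma adjusted p = 1.13e-06) from the latter. The calcium-binding protein S100a4 differed from Ly49E-CD8aa+ by 3.93 (SE 0.192), the uridine phosphorylase Upp1 by 3.90 (SE 0.171), the protease inhibitor Serpinb1a by 3.32 (SE 0.335) and the chromatin organiser Satb1 by 2.90 (SE 0.254). The adhesion receptor Cd44 (2.26, SE 0.163), the hypoxia-related factor Epas1 (2.10, SE 0.139), the chemokine receptor Cxcr4 (1.93, SE 0.265) and the inhibitory receptor Ctla4 (1.57, SE 0.221) were higher as well. Nr1d1, a repressor of the circadian clock, was higher by 3.40 (SE 0.205, adjusted p = 2.67e-05). Of the other clock genes, Per3 was lower by a log2 difference of -0.46 (SE 0.0851, adjusted p = 0.0247), while Nr1d2 (0.09), Per1 (0.17), Per2 (-0.11), Dbp (0.14), Arntl (0.39) and Clock (-0.03) did not pass.

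Both CD8aa+ populations were higher than Ly49E+CD8aa- in the incretin receptor gene Glp1r, at 10.37 ± 0.0455 and 10.32 ± 0.0434 against 9.31 ± 0.0564 (SD, n = 3). The log2 difference of Ly49E+CD8aa- minus Ly49E-CD8aa+ was -1.01 (SE 0.0618, limma adjusted p = 2.95e-05). The same difference was -1.17 (SE 0.09) for Il34, a ligand of the CSF-1 receptor, -0.74 (SE 0.0729) for Cd200r2, -0.56 (SE 0.087) for the ectonucleotidase Entpd1 and -0.53 (SE 0.0806) for the transcriptional repressor Prdm1. The metallothionein genes Mt1 (-0.89, SE 0.103, adjusted p = 0.00176) and Mt2 (-1.53, SE 0.314, adjusted p = 0.043) were lower in Ly49E+CD8aa- than in Ly49E-CD8aa+. For both genes Ly49E+CD8aa+ lay nearer Ly49E+CD8aa- (positions 0.614 and 0.608). Neither was among the 72 genes called higher in both CD8aa+ populations.

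Ly49E+CD8aa+ had less Ctsh, which encodes cathepsin H, than either other population, with 4.94 ± 0.226 against 6.68 ± 0.181 in Ly49E+CD8aa- and 6.71 ± 0.487 in Ly49E-CD8aa+ (SD, n = 3, limma adjusted p = 0.00393 and 0.0303). Adh1 was the 1 gene higher than in both.

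The 17 genes lower in both Ly49E+ populations, such as Siglech, Cd180 and Cybb, exceeded the Ly49E+CD8aa+ and Ly49E+CD8aa- levels by medians of 1.47 and 1.46 in Ly49E-CD8aa+, with the lowest at 0.618 and 0.572. Admixed B cells or macrophages would raise their own markers. The B cell list had medians of 0.063 ± 0.0709 and 0.153 ± 0.0567 (SE over 13 members) and the macrophage list 0.0237 ± 0.0774 and 0.0518 ± 0.0875 (18 members). The 17 genes were chosen for passing in both comparisons and these lists were not, so lower medians do not decide the question. Blnk of the B cell list is itself among the 17. The markers of plasmacytoid dendritic cells given below also had medians under the lowest of the 17. Of the 17, Siglech read 7.84, 7.26 and 7.43 and Cybb 6.97, 6.09 and 6.16 on Ly49E-CD8aa+ replicates 1, 2 and 3. Cd180, Cd209d, Pld4, Rnase6, Ly6d and Klra17 were also highest on replicate 1, while Mpeg1 and Blnk were highest on replicate 2. On each replicate these genes read above every array of both Ly49E+ populations. Replicate 1 had the lowest array weight (0.508), so its peak does not decide between admixture and expression. Plasmacytoid dendritic cells in the sort may contribute. The CD45+ CD3- gate would not exclude these cells, although the CD8aa+ gate would exclude those without CD8aa at the surface and purity was over 98%. Of 25 further markers of these cells, 23 were measured, 5 of them in fixed lists, with medians of 0.11 and 0.26, 16 and 15 higher, 0 past the threshold by limma (8 and 9 at an unadjusted p under 0.05), and camera p = 5.03e-05 and 0.00476, or p = 0.0526 and 0.144 with an estimated correlation. Plac8, St8sia4 and Lag3, at 10.65, 10.28 and 10.21 in Ly49E-CD8aa+, read 10.84, 10.31 and 10.34 in Ly49E+CD8aa+ and 10.54, 10.32 and 9.85 in Ly49E+CD8aa-, levels that would hide a small share. Some markers at lower levels were not raised in either comparison. Pacsin1, Unc93b1, Atp1b1 and Irf7 were at 6.15, 7.37, 7.50 and 8.13 in Ly49E-CD8aa+. They read 6.20, 7.37, 7.64 and 8.25 in Ly49E+CD8aa+ and 6.55, 7.43, 7.93 and 8.34 in Ly49E+CD8aa-. Others read higher in Ly49E-CD8aa+, such as Flt3 (5.59 against 5.02 and 5.06) and Tlr7 (6.03 against 5.42 and 5.51). Admixture cannot be told apart from expression by Ly49E-CD8aa+, while conventional dendritic cells, such as carry Clec9a and Cd209a, stay open.

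The 72 genes higher in both CD8aa+ populations differed less than the 215 higher in Ly49E+CD8aa-, with medians of the smaller difference of 0.6 and 1.15 and highest values of 1.44 (Rnf180) and 5.29 (Ncr1). Compression of high signals stays open, since the 4 of 72 (5.56%) at or above the Cd8a level of 11.42 were counted over different probes, whose levels cannot be compared. Cells like the CD8aa+ populations admixed in Ly49E+CD8aa- may cap these differences at that of Cd8a, and 0 of 71 other genes exceeded Cd8a by more than 2 SE in both comparisons, against 70 of the 215. The rule of both comparisons was set after Adh1 had been seen to exceed Cd8a in 1 of them, 2.05 against 1.13, and taken singly 2 genes did so in each comparison, Adh1 and Gpx8, and Ptpn5 and Rnf180. Without the margin of 2 SE, 6 of the 71 genes and 107 of the 215 lay above Cd8a in both comparisons. Taken at face value, Cd8a differences of only 1.13 and 1.16 mean that a cap at Cd8a would take a large share of admixed cells. The sort purity over 98% argues against such a share. A small share, which would not cap the differences at that of Cd8a, cannot be told apart from weaker differences between the populations.

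Cd8b1 was higher in Ly49E+CD8aa- than in both CD8aa+ populations, by 3.04 over Ly49E-CD8aa+ (SE 0.111). Cross-hybridisation with Cd8a transcript would raise Cd8b1 where Cd8a is high, yet Cd8a differed by -1.13 and -1.16 in Ly49E+CD8aa- (SE 0.0841). Admixed alpha beta T cells may contribute, although NOD-SCID mice lack mature T cells and the CD3- gate and a purity over 98% would leave few. Cd5, Cd6, Cd3d, Cd3e and Cd3g had medians of -0.209 and -0.219 over Ly49E+CD8aa+ and Ly49E-CD8aa+, with Cd5 at -0.004 and -0.037 and Cd6 at -0.033 and 0.02. But Cd3e read 11.67 in Ly49E-CD8aa+, which would hide a small share. Of 23 T lineage genes, 6 were higher and 1 lower than in Ly49E-CD8aa+ (camera adjusted p = 0.000962, or 0.0674 with an estimated correlation). Against Ly49E+CD8aa+ 4 were higher and 2 lower (camera adjusted p = 0.00731, or 0.139 with an estimated correlation). A row of several T cell receptor segments was higher than in Ly49E-CD8aa+ by 1.885 (limma adjusted p = 0.00621). Admixture therefore cannot be told apart from expression of Cd8b1 by the population itself, which was not tested further.

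Over other splits of the arrays into groups of the same sizes, 1 of 100 drawn splits of the 9 arrays gave as many genes by the F test, the real one with 405. So high a count was thus rare among random divisions of all 9 arrays. The highest other split gave 299 and was the 1 other drawn that kept the 3 Ly49E+CD8aa- arrays together, and the highest of the rest gave 10. The count may rest largely on the separation of Ly49E+CD8aa-, although only 1 drawn split shows this. It does not test the division of the CD8aa+ cells by Ly49E. With 10 splits of 6 arrays, the splits are too few for a share under 0.05. The real values were 26, 339 and 429 for the Ly49E comparison, the CD8aa comparison and the comparison of the populations with a single marker, each given by 1 of 10 splits, and the highest of the others were 0, 0 and 1.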
